A study of Mus musculus with 30 samples.

How the data were processed

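RNA from the livers of male mice was measured on 30 Affymetrix arrays in 10 groups of 3. Per the submitters' processing notes, the values were made by RMA, a method that corrects background, normalizes between arrays and summarizes the probes of each probe set; the version and the settings are not given in the sources used here. The deposited values were log2 probe set summaries, and array medians lay between 5.36 and 5.44 log2 units. The number of arrays limits the precision. Raw scanner files were not used here, so the background correction and the probe summaries were taken as the authors made them.

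The table held 45037 probe sets. Of these, 34945 were annotated to a single gene, 932 to several genes and 9160 to none, and the single-gene probe sets covered 18194 genes. The gene identifiers of 34741 of them were found in a RefSeq gene table for assembly GRCm38.p6, which was used for names only, and 0 symbols were updated. For each gene, the probe set with the highest mean over all 30 arrays was used. A gene was tested when that probe set exceeded the array's median on at least 3 arrays, which left 12795 genes. Probe sets with several genes or none were left out of the comparisons and were fitted apart.

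A single linear model with a mean per group was fitted to all arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, two-sided moderated tests). It had 20 residual degrees of freedom, and the prior added 3.62. Each of 14 comparisons was adjusted over the genes tested by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. There were 6 treatment effects (each treated group against corn oil in the same genotype), 4 comparisons of genotypes under corn oil, and 4 differences of a treatment effect from that in wild type mice. The design states 5 mice per group and 3 arrays were used for each, but the labels do not say that every array is a separate mouse; the p-values measure the spread between these samples.

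The labels and the protocol differ on duration. Cyproterone acetate is labelled as 6 days in wild type and hCAR/hPXR mice and as 3 days in CARko/PXRko mice, while the protocol describes 3 days of treatment for all. The corn oil controls are labelled 3 days. Differences in the cyproterone acetate effect between CARko/PXRko and wild type mice therefore carry genotype and labelled duration together. By the same labels, the cyproterone acetate effects in wild type and hCAR/hPXR mice set 6-day arrays against 3-day controls. These effects, and what they share with the CARko/PXRko effect, carry labelled duration too.

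Gene lists, comparisons, alternatives and the rule for naming genes were fixed before the data were examined. For each treatment effect, the genes named were the 10 largest rises and the 10 largest falls among called genes whose 3 treated arrays all lay outside the range of the 3 control arrays. For genotypes and for differences of effects the number was 5 each way, the latter by adjusted p alone. Nr1i3, Nr1i2, Cyp2b10 and Cyp3a11 were always named, as were up to 4 members of each list with the smallest p in a comparison. Genes taken from lists added later were chosen after the data were seen.

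There were 32 lists with 477 memberships, of which 418 matched a gene with its own probe set, 2 of them through an older symbol. Lists with at least 4 measured members were tested with camera from limma at a preset inter-gene correlation of 0.01 and again with an estimated correlation, and each version was adjusted over 406 tests. The test fry was run as an alternative. Some genes are on several lists, so results of such lists are not independent. Gstm3 and Ephx1 are both NRF2 targets and other CAR and PXR responsive genes, and Gstm3 is also a conjugation enzyme. Counts of called members are given over all genes tested and adjusted over the list alone. Further lists were written after unusual arrays had been seen: 17 skeletal muscle, 5 brown fat, 3 adrenal cortex and 5 squamous epithelium genes measured, and then 11 glucocorticoid-responsive genes and 6 dendritic and B cell genes.

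Alternatives were no filter on dim genes, a filter at the 75th percentile, quantile normalization applied again, arrays centred on their median, the mean of a gene's probe sets, eBayes with trend and robust, array weights, the replicate block, only the groups compared, an added 2-fold threshold, and leaving out each array in turn. A set of 3 rules for leaving out arrays was added after seeing the data. Agreement between comparisons was set against 100 simulations with no effect that kept the covariance between genes.

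The procedure was tested on simulated data made for each comparison on 12795 genes, with 20 simulations per fold size and 200 changed genes in each. For 2-fold changes, recovery was 74.5%, 73.4% and 76.2% for the DCB effect in wild type, hCAR/hPXR and CARko/PXRko mice, and 76.3%, 74.3% and 75.8% for the CPA effect. For 4-fold changes, the same comparisons gave 96.7%, 97.0%, 96.5%, 96.4%, 96.3% and 96.5%. Differences of the DCB effect recovered 45.5% (hCAR/hPXR) and 43.6% (CARko/PXRko) of 2-fold changes and 89.9% and 90.9% of 4-fold changes. For the CPA effect these were 41.7%, 43.0%, 91.0% and 90.7%. The share of false genes among all called genes reached 38.0% for the DCB effect in CARko/PXRko mice at 2-fold and 32.1% for the DCB effect in hCAR/hPXR mice at 4-fold, although the median per simulation was 0.0% and 0.3% there. A few simulations with many false calls account for the gap between both figures. Recovery was nearly the same for each treatment effect at a given fold size, while the real groups differed in spread. With only the groups compared, the standard error of Cyp2b10 was 0.23 for CPA and 0.93 for DCB in wild type mice. Arrays with transcripts of other tissues are a further difference between the real groups. The recovery figures therefore do not tell how well a given comparison recovers changes.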

Results

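Liver gene expression was measured in male mice given corn oil, 1,4-dichlorobenzene (DCB, a solvent and mothball ingredient, 600 mg/kg) or cyproterone acetate (CPA, a steroidal antiandrogen and progestin, 160 mg/kg) by mouth. The mice were wild type, hCAR/hPXR (the mouse receptors CAR and PXR replaced by the human ones), CARko/PXRko (lacking both receptors) or PXRko. CAR and PXR are nuclear receptors that switch on drug-metabolizing genes in the liver. There were 3 arrays in each of 10 groups, 30 in all, and PXRko mice received corn oil alone. Changes are log2 differences between group means ± SE with 3 arrays per group, and p-values are adjusted values from limma unless stated. For the largest changes named in a treatment effect, all 3 treated arrays lay outside the range of the 3 control arrays.

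The genotypes were compared under corn oil to see how the receptor genes and the liver at rest differed. Nr1i3, which encodes mouse CAR, fell by 3.29 ± 0.21 in hCAR/hPXR mice (adjusted p = 4.41e-10) and fell by 3.35 ± 0.21 in CARko/PXRko mice (adjusted p = 5.7e-10). Nr1i2, which encodes mouse PXR, fell by 2.74 ± 0.23 in hCAR/hPXR mice (adjusted p = 9.89e-08), fell by 2.94 ± 0.23 in CARko/PXRko mice (adjusted p = 3.49e-08) and fell by 3.05 ± 0.23 in PXRko mice (adjusted p = 3.44e-08). The Nr1i2 means in these 3 groups, 4.48 to 4.78, lay under the array medians of 5.36 to 5.44, so its falls are lower bounds. In PXRko mice Nr1i3 was 0.20 ± 0.21 above wild type and was not called. The probe sets read mouse transcripts, so Nr1i3 and Nr1i2 do not tell hCAR/hPXR from CARko/PXRko mice. Tmem223, a mitochondrial membrane protein gene, does: its mean was 7.57 ± 0.19 (SD, n = 3) in hCAR/hPXR and 9.64 ± 0.01 in wild type mice, and it fell by 2.07 ± 0.13 in the former (adjusted p = 4.41e-10).

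Few other genes were called between genotypes at rest. Of 12795 genes, 3 were called in hCAR/hPXR mice, 5 in CARko/PXRko mice and 3 in PXRko mice against wild type, and 2 in CARko/PXRko against PXRko mice. Unadjusted p-values under 0.05 numbered 185, 424, 220 and 353, each under the share of 0.05 expected with no difference. With only the groups compared they numbered 596, 704, 540 and 541. The fit to all arrays was thus cautious for these groups, and few calls do not show that the livers were alike. In CARko/PXRko mice Tomm40l fell by 1.31 ± 0.20 (adjusted p = 0.00315), while Hamp, the gene of the iron hormone hepcidin, rose by 1.92 ± 0.31 (adjusted p = 0.00885) and Pla2g12a by 1.55 ± 0.27 (adjusted p = 0.0143). Pla2g12a rose in PXRko mice too, by 1.56 ± 0.27 (adjusted p = 0.0319), as did Cyp2g1, by 2.50 ± 0.44 (adjusted p = 0.0388). Hamp, though not called there, lay at 12.65 to 13.76 in hCAR/hPXR and 12.75 to 13.31 in PXRko mice, against 11.31 to 11.88 in wild type mice. Likewise, Pla2g12a lay at 8.63 to 8.91 in hCAR/hPXR against 7.16 to 8.01 in wild type mice without a call. Neither gene therefore sets apart the genotypes in which it was called. Against PXRko mice, CARko/PXRko mice had less Nr1i3 (-3.56 ± 0.21, adjusted p = 1.57e-10) and less Tomm40l (-1.18 ± 0.20, adjusted p = 0.0229). In hCAR/hPXR mice, where Nr1i3 fell too, Tomm40l was not lower: it lay at 8.99 to 9.36 against 8.19 to 8.50 in wild type mice. The list of other CAR and PXR responsive genes was shifted up in hCAR/hPXR mice (camera adjusted p = 0.000113; adjusted p = 0.00765 with an estimated correlation), with 0 of 11 members called and 2 when adjusted over the list alone. Without corn oil CARko/PXRko replicate 1, or without wild type replicate 2, 3 of the 5 genes called in CARko/PXRko mice were still called, and Hamp and Pla2g12a were not. In PXRko mice, and in CARko/PXRko against PXRko mice, 1 gene stayed called whichever array was left out (Nr1i2 and Nr1i3, respectively). Corn oil PXRko replicate 3 carried muscle transcripts (median 1.65 log2 units above wild type corn oil), as did corn oil CARko/PXRko replicate 2 (7.48). Without the 4 arrays with such transcripts, 2 of the 3 PXRko calls, 4 of the 5 CARko/PXRko calls and 1 of the 2 calls between both were kept.

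**Figure D1:**
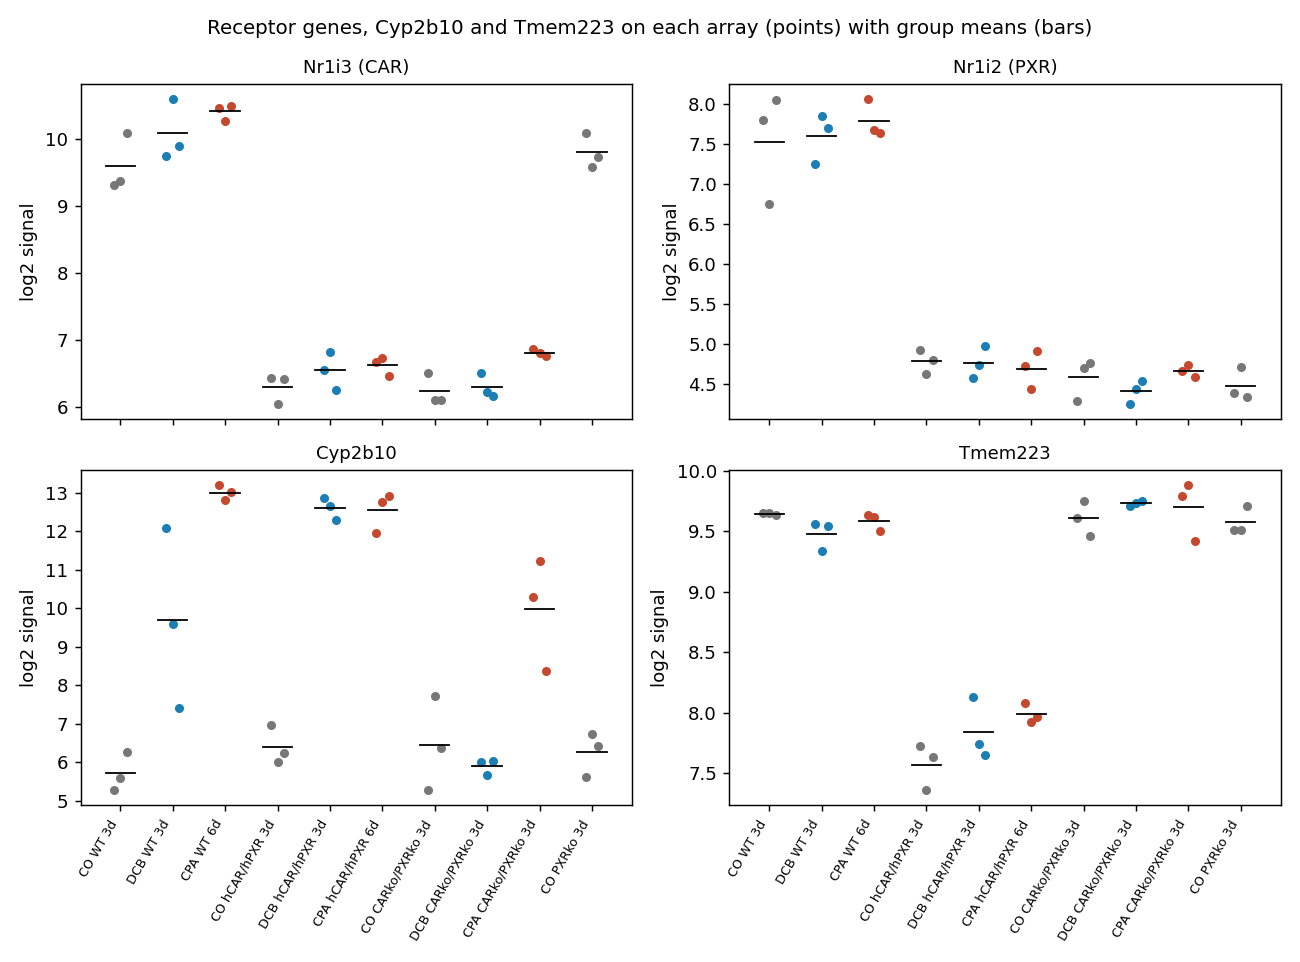
Log2 signal of Nr1i3, Nr1i2, Cyp2b10 and Tmem223 on each of 30 arrays (points) with group means (bars), by treatment and genotype. Cyp2b10 means were 5.71 under corn oil and 13.00 under CPA in wild type mice, and 6.46 and 9.97 in CARko/PXRko mice.

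Under DCB in wild type mice Cbr3, a carbonyl reductase gene driven by the oxidative stress factor NRF2, rose by 5.11 ± 0.38 (adjusted p = 2.35e-08). Cyp2b10, the standard CAR target in mouse liver, rose by 3.98 ± 0.77 (adjusted p = 0.0083), from 5.71 ± 0.51 (SD, n = 3) to 9.69 ± 2.34. Its relative Cyp2c55 rose by 3.60 ± 0.51 (adjusted p = 0.000405). The export pump gene Abcc4 rose by 3.44 ± 0.59 and the fetal liver gene Afp by 2.95 ± 0.54. The glutathione transferases that rose included Gstm3 (2.83 ± 0.47), Gsta2 (2.49 ± 0.37), Gstm4 (2.33 ± 0.32) and Gstm2 (1.87 ± 0.26). The heat shock gene Hspb1 (2.89 ± 0.48) and the transferrin receptor gene Tfrc (2.28 ± 0.45) rose as well. Further NRF2 targets that rose were Srxn1 (2.15 ± 0.25), Nqo1 (2.14 ± 0.36) and Gsr (1.20 ± 0.19). Ugdh (1.42 ± 0.18), Ephx1 (1.01 ± 0.21) and Cyp2c29 (0.93 ± 0.15) rose with them. Glul, the glutamine synthetase of hepatocytes around the central vein, fell by 1.46 ± 0.34 (adjusted p = 0.0361). The other large falls were in 1700001C19Rik (-1.21 ± 0.25), Hyi (-0.97 ± 0.20), Slc17a5 (-0.87 ± 0.17), Prxl2a (-0.84 ± 0.19), Amy1 (-0.83 ± 0.18), Tle4 (-0.66 ± 0.14), Tgfbr1 (-0.63 ± 0.12), Parva (-0.63 ± 0.15) and Mettl26 (-0.63 ± 0.14). Cyp3a11, a PXR target whose signal was already 14.50 ± 0.10 (SD, n = 3) under corn oil, was 0.13 ± 0.09 higher and was not called. It was at least 14.39 on every array, and the highest signal of any probe set was 15.21 to 15.34 per array. Neither the size of its changes nor a missing call therefore measures a PXR response here.

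In wild type mice under DCB, of 16 NRF2 target genes measured, 7 rose, 0 fell and 9 were not called; 12 rose when adjusted over the list alone, and camera gave adjusted p = 1.27e-19 (adjusted p = 0.00517 with an estimated correlation). Among other CAR and PXR responsive genes, 2 of 11 rose and 4 did when adjusted over the list alone (camera adjusted p = 1.04e-05; adjusted p = 0.00517 with an estimated correlation). Gstm3 and Ephx1, which both rose, are on this list and on that of NRF2 targets, so the lists are not independent. Of 27 conjugation enzymes, Gstm3 again among them, 7 rose, or 8 with 1 fall when adjusted over the list alone. Camera's p of 8.73e-07 became an adjusted p = 0.149 with an estimated correlation. Of 11 CYP2B and CYP2C enzymes, 3 rose, and also 3 when adjusted over the list alone (camera adjusted p = 0.00556; adjusted p = 0.343 with an estimated correlation). In all, 94 genes were called, 78 higher and 16 lower. Leaving out 1 array gave 50 (corn oil replicate 1), 48 (corn oil replicate 2), 62 (corn oil replicate 3) or 37 (DCB replicate 1). Of the 20 largest changes, 7 stayed called whichever array was left out: all 10 falls lost their call at least once, as did Cyp2b10, Afp and Tfrc. Cyp2b10 stood at 3.77 without corn oil replicate 1 (adjusted p = 0.0663), at 2.78 without DCB replicate 1 (adjusted p = 0.0993) and at 3.98 with only the groups compared (adjusted p = 0.0846), where its standard error was 0.93.

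Under DCB in hCAR/hPXR mice Cyp2b10 rose by 6.20 ± 0.77 (adjusted p = 3.51e-05), from 6.41 ± 0.50 to 12.60 ± 0.29 (SD, n = 3). Cbr3 rose by 5.82 ± 0.38 (adjusted p = 1.47e-09). Abcc4 rose by 4.29 ± 0.59, Nqo1 by 3.39 ± 0.36, Srxn1 by 3.14 ± 0.25, Cyp2c55 by 3.20 ± 0.51, Amn by 3.04 ± 0.28, Tfrc by 3.03 ± 0.45 and Afp by 2.89 ± 0.54. Cyp1a1, the classical target of the dioxin receptor AHR, rose by 3.55 ± 0.74 (adjusted p = 0.00515). Alas1, the first enzyme of heme synthesis, rose by 2.32 ± 0.39, and the transferases Gstm2, Gstm4 and Gstt3 rose by 2.61 ± 0.26, 2.42 ± 0.32 and 2.37 ± 0.37. The falls included the glucuronidation gene Ugt2b38 (-2.77 ± 0.60), the transcription factor gene Klf10 (-2.69 ± 0.55), Hectd2os (-2.62 ± 0.61), the steroid enzyme Hsd17b6 (-2.52 ± 0.60) and Mme (-2.37 ± 0.66). G6pc, which releases glucose from the liver, fell by 2.29 ± 0.57, and Aox3 (-2.10 ± 0.40), the growth factor receptor Egfr (-2.07 ± 0.50), Gbp6 (-2.07 ± 0.55), Slc1a2 (-2.05 ± 0.61) and Cyp2c23 (-1.68 ± 0.29) fell too. Cyp3a11 was not called.

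Of 16 NRF2 target genes, 8 rose in hCAR/hPXR mice under DCB and 11 did when adjusted over the list alone (camera adjusted p = 1.04e-13; adjusted p = 0.00929 with an estimated correlation). Among other CAR and PXR responsive genes 4 of 11 rose, 6 when adjusted over the list alone (camera adjusted p = 3.04e-05; adjusted p = 0.00517 with an estimated correlation). Conjugation enzymes rose in 8 of 27 cases, 10 when adjusted over the list alone (camera adjusted p = 2.92e-08; adjusted p = 0.099 with an estimated correlation). Kupffer cell and macrophage markers fell in 7 of 11 cases, 10 when adjusted over the list alone, with Adgre1 at -1.07 ± 0.20, Clec4f at -1.04 ± 0.21 and Csf1r at -1.26 ± 0.27 (camera adjusted p = 5.25e-07; adjusted p = 0.27 with an estimated correlation). Of 8 lymphocyte and antigen presentation markers 4 fell, also 4 when adjusted over the list alone, and these were H2-Aa (-1.89 ± 0.47), H2-Ab1 (-1.80 ± 0.51), H2-Eb1 (-1.64 ± 0.48) and Cd74 (-1.31 ± 0.32); camera gave adjusted p = 0.0152 (adjusted p = 0.31 with an estimated correlation). Stellate cell and fibroblast markers fell in 3 of 11 cases, also 3 when adjusted over the list alone, with Lrat at -1.52 ± 0.34 (camera adjusted p = 0.00985; adjusted p = 0.538 with an estimated correlation). In all, 978 genes were called, 421 higher and 557 lower (43.0% higher), against 558 higher and 311 lower (64.2% higher) with arrays centred on their median. Leaving out 1 array gave 337 genes without corn oil replicate 2 and 526 without corn oil replicate 1. Without DCB replicate 3, whose mean correlation with its group was 0.951, there were 686, 369 higher and 317 lower, and 499 of the 978 calls were kept. With only the groups compared 82 genes were called. Of the 20 largest changes 12 stayed called whichever array was left out; 8 of the falls, all but Klf10 and Aox3, lost their call at least once.

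Under DCB in CARko/PXRko mice Cbr3 rose by 4.33 ± 0.38 (adjusted p = 7.03e-07), Srxn1 by 1.86 ± 0.25 (adjusted p = 0.000376) and Abcc4 by 3.23 ± 0.59 (adjusted p = 0.0152). Cyp2b10 was -0.56 ± 0.77 from corn oil (adjusted p = 0.918), with means of 5.90 ± 0.21 and 6.46 ± 1.23 (SD, n = 3). Corn oil replicate 2 had the highest Cyp2b10 of the controls, 7.73 against 5.28 and 6.37, and without it the difference was 0.07 (adjusted p = 0.985). The ubiquitin ligase adaptor Fbxo2 rose by 2.50 ± 0.29, Afp by 2.84 ± 0.54, the carbonyl reductase Cbr1 by 1.66 ± 0.20, the heme transporter Slc48a1 by 1.65 ± 0.27, Gstm2 by 1.47 ± 0.26, Vat1 by 1.41 ± 0.25 and Ugdh by 1.17 ± 0.18. Sbsn, a gene of squamous epithelium, rose by 2.95 ± 0.54, and replicate 2 of this group had a median of 3.19 log2 units above wild type corn oil over 5 squamous epithelium genes. Of 16 NRF2 target genes 3 rose, 0 fell and 11 rose when adjusted over the list alone (camera adjusted p = 1.22e-16; adjusted p = 0.00517 with an estimated correlation). Of 27 conjugation enzymes 2 rose, or 4 with 2 falls when adjusted over the list alone (camera adjusted p = 0.00178; adjusted p = 0.374 with an estimated correlation). For CYP2B and CYP2C enzymes 0 of 11 were called, and 0 when adjusted over the list alone, while camera found a shift down (adjusted p = 0.00212; adjusted p = 0.324 with an estimated correlation).

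The 15 genes called for DCB in CARko/PXRko mice were all higher, against 14 higher and 2 lower (87.5% higher) with arrays centred on their median, and unadjusted p-values under 0.05 numbered 1036. Arrays of this genotype carried transcripts of other tissues: medians over 17 skeletal muscle genes were 7.48 log2 units above wild type corn oil in corn oil replicate 2, 7.08 in DCB replicate 3 and 2.57 in DCB replicate 2, and DCB replicate 3 was 5.00 above over 3 adrenal cortex genes. The count was 72 without DCB replicate 1, 69 without corn oil replicate 2, and 6 without corn oil replicate 1 or 3. Cbr3, Fbxo2, Srxn1, Cbr1 and Slc48a1 stayed called whichever array was left out; Abcc4, Sbsn, Afp, Gstm2 and Vat1 lost their call without corn oil replicate 1 or 3. With only the groups compared 0 of the 15 genes were called, and without the 4 arrays with muscle transcripts 4 of the 15 were.

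**Figure D2:**
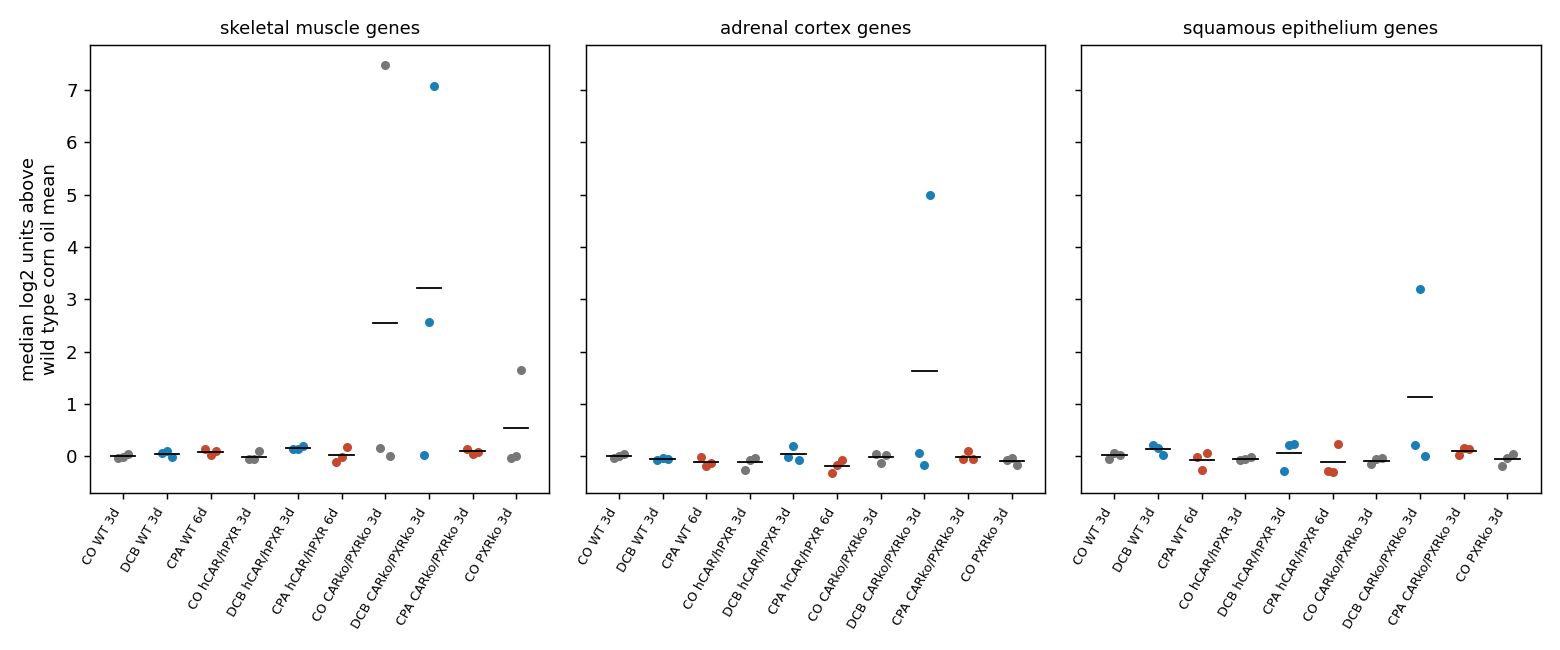
Median over skeletal muscle, adrenal cortex and squamous epithelium genes on each array (points), in log2 units above the wild type corn oil mean, with group means (bars). Corn oil CARko/PXRko replicate 2 reached 7.48 and DCB CARko/PXRko replicate 3 reached 7.08 for muscle genes.

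The DCB effect was compared between genotypes to see what the receptors changed. With limma, 0 of 12795 genes were called for a different effect in hCAR/hPXR and 0 in CARko/PXRko mice than in wild type mice. Unadjusted p-values under 0.05 numbered 398 and 324, both under the share of 0.05 expected with no difference. The absence of calls therefore does not show equal effects. For CARko/PXRko mice the count was 2 without DCB CARko/PXRko replicate 1, 1 without DCB wild type replicate 2 and 3 without DCB wild type replicate 3. Cyp2b10 differed by 2.22 ± 1.09 in hCAR/hPXR mice (adjusted p = 1) and by -4.54 ± 1.09 in CARko/PXRko mice (adjusted p = 0.875). Without that last array, which had the lowest Cyp2b10 of its group, the latter was -5.68 with adjusted p = 0.0327. As a group, the 11 CYP2B and CYP2C enzymes moved down in CARko/PXRko against wild type mice, with a median of -1.19 (camera adjusted p = 2.96e-09; adjusted p = 0.0292 with an estimated correlation), and 3 were lower when adjusted over the list alone. The medians of the effects themselves were 0.43 in wild type and -0.68 in CARko/PXRko mice, and the latter includes corn oil replicate 2 and DCB replicates 2 and 3 with their transcripts of other tissues. Without the 4 arrays with muscle transcripts the median difference was -0.63 (camera adjusted p = 0.00184; adjusted p = 0.272 with an estimated correlation), and without the 2 with the most it was -1.22 (adjusted p = 3.07e-08; adjusted p = 0.0664 with an estimated correlation). Without the 4 arrays least like their group it was -1.59 (adjusted p = 5.18e-10; adjusted p = 0.0274 with an estimated correlation). With 1 array left out it ran from -2.07 to -1.01, and the p with an estimated correlation from 0.00469 to 0.171. The 3 rules were chosen after seeing the data; leaving out 1 array was planned for counts and genes and was extended to this list afterwards. NRF2 target genes had a median difference of -0.20 and 0 of 16 members called, also 0 when adjusted over the list alone (camera adjusted p = 0.0421; adjusted p = 0.538 with an estimated correlation). Kupffer markers moved down in hCAR/hPXR against wild type mice (median -0.54, camera adjusted p = 4.89e-05; adjusted p = 0.366 with an estimated correlation). Of the genes that DCB raised, 67 were called in both wild type and hCAR/hPXR mice against 2.6 for independent lists, and 13 in both wild type and CARko/PXRko mice against 0.1; 10 against 0.7 were lower in both of the former. Pearson's r of the changes across genes, which are not independent replicates, was 0.67 for wild type with hCAR/hPXR mice (-0.74 to 0.57 in simulations with no effect) and 0.50 for wild type with CARko/PXRko mice (-0.63 to 0.60). These ranges rest on a spread pooled over all groups, not on that of the groups compared.

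Under CPA in wild type mice Cyp2b10 rose by 7.28 ± 0.77 (adjusted p = 6.73e-06), to 13.00 ± 0.20 (SD, n = 3), and Cyp2c55 by 4.00 ± 0.51 (adjusted p = 7.92e-05). By the mean of the gene's probe sets, Cyp2b10 rose by 8.44 here and by 5.20 under DCB. The probe sets added to that mean had corn oil means of 4.41 and 4.02. These lay under the array medians of 5.36 to 5.44, so both rises are lower bounds. Sult1e1, the sulfotransferase that inactivates estrogens, rose by 6.08 ± 0.69 (adjusted p = 1.78e-05), and Cyp17a1, a steroid hydroxylase higher in female than male mouse liver, by 3.97 ± 0.69 (adjusted p = 0.0035). Cyp3a44, a further female-biased gene, rose by 2.15 ± 0.25, and Cyp3a11, near the top of the scale as noted, was called at 0.45 ± 0.09 (adjusted p = 0.0109). The carboxylesterase Ces2a rose by 2.08 ± 0.20, Gstm3 by 3.58 ± 0.47, Gstm2 by 2.09 ± 0.26, 1810053B23Rik by 5.02 ± 0.72, Myom3 by 3.79 ± 0.70, the metallothionein Mt2 by 3.60 ± 0.79, Nebl by 3.27 ± 0.22, Acnat2 by 3.22 ± 0.67 and the acute phase gene Orm3 by 2.39 ± 0.51. Serpina6 and Serpina7, which encode the blood carriers of glucocorticoid and thyroid hormone, fell (-2.90 ± 0.42 and -3.29 ± 0.67). Further falls were in Cib3 (-3.54 ± 0.79), Ugt2b38 (-2.77 ± 0.60), 1810008I18Rik (-2.29 ± 0.49), Nrep (-2.19 ± 0.48), Ifi27l2a (-1.97 ± 0.40) and the antibody gene Igha (-1.83 ± 0.43). The antigen presentation genes H2-Aa (-2.41 ± 0.47), H2-Ab1 (-2.31 ± 0.51) and Cd74 (-1.30 ± 0.32) and the interferon-stimulated gene Usp18 (-1.71 ± 0.29) fell.

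In wild type mice under CPA, of 11 CYP2B and CYP2C enzymes 3 rose, 5 when adjusted over the list alone (camera adjusted p = 2.92e-08; adjusted p = 0.0453 with an estimated correlation), and of 4 CYP3A enzymes 2 rose, 4 when adjusted over the list alone (adjusted p = 8.62e-10; adjusted p = 0.00527 with an estimated correlation). Other CAR and PXR responsive genes rose in 2 of 11 cases, 7 when adjusted over the list alone (adjusted p = 2.52e-11; adjusted p = 0.000106 with an estimated correlation). Conjugation enzymes rose in 6 of 27 cases, 8 when adjusted over the list alone (adjusted p = 9.05e-09; adjusted p = 0.0843 with an estimated correlation). Interferon-stimulated genes fell in 6 of 17 cases, 13 when adjusted over the list alone (adjusted p = 1.04e-13; adjusted p = 0.0704 with an estimated correlation). Lymphocyte and antigen presentation markers fell in 3 of 8 cases, 4 when adjusted over the list alone (adjusted p = 1.77e-05; adjusted p = 0.0428 with an estimated correlation), and Kupffer markers in 2 of 11, 9 when adjusted over the list alone (adjusted p = 1.34e-08; adjusted p = 0.19 with an estimated correlation). NRF2 target genes, by contrast, had 1 of 16 called, 3 when adjusted over the list alone, and a median of -0.04, or 0.01 with arrays centred on their median (adjusted p = 0.17). In all 143 genes were called, 62 higher and 81 lower, and with only the groups compared 774 were. Leaving out 1 array gave 41 (corn oil replicate 1), 44 (corn oil replicate 2), 112 (corn oil replicate 3), 38 (CPA replicate 1), 81 (CPA replicate 2) or 69 (CPA replicate 3). Of the 20 largest changes 9 stayed called whichever array was left out: Cyp2b10, Sult1e1, 1810053B23Rik, Cyp2c55, Cyp17a1, Myom3, Gstm3, Nebl and Serpina6.

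Under CPA in hCAR/hPXR mice Sult1e1 rose by 7.59 ± 0.69 (adjusted p = 4.31e-07) and Cyp17a1 by 5.28 ± 0.69 (adjusted p = 3.97e-05). Cyp2b10 rose by 6.13 ± 0.77 (adjusted p = 2.76e-05), to 12.53 ± 0.51 (SD, n = 3). Lcn2 (4.10 ± 0.78), Mt2 (3.78 ± 0.79) and Scara5 (3.85 ± 0.62) rose, as did 1810053B23Rik (5.05 ± 0.72), Rnase2a (4.56 ± 1.24), Acnat2 (3.84 ± 0.67), Myom3 (3.75 ± 0.70), the female-biased Fmo2 (3.69 ± 0.45), Gstt3 (2.63 ± 0.37) and Gadd45b (2.10 ± 0.35). The antigen presentation gene H2-Aa fell by 4.99 ± 0.47 (adjusted p = 5.6e-07), and H2-Eb1 (-3.50 ± 0.48), H2-Ab1 (-3.47 ± 0.51) and Cd74 (-2.74 ± 0.32) fell with it. Other falls were in Serpina6 (-4.00 ± 0.42), Serpina7 (-3.45 ± 0.67), Ugt2b38 (-3.39 ± 0.60), the interferon-induced Gbp6 (-3.19 ± 0.55), Cib3 (-2.88 ± 0.79), the chemokine gene Cxcl9 (-2.75 ± 0.64), Usp18 (-2.46 ± 0.29) and Ifit2 (-1.59 ± 0.22). The macrophage markers Adgre1 (-1.54 ± 0.20), Csf1r (-1.69 ± 0.27) and Cd5l (-1.65 ± 0.30) fell too. Cyp3a11 was not called.

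Interferon-stimulated genes fell in 13 of 17 cases in hCAR/hPXR mice under CPA, 15 when adjusted over the list alone (camera adjusted p = 1.36e-18; adjusted p = 0.0252 with an estimated correlation). Lymphocyte and antigen presentation markers fell in 5 of 8 cases, also 5 when adjusted over the list alone (adjusted p = 2.6e-07; adjusted p = 0.0121 with an estimated correlation), and Kupffer markers in 8 of 11, 9 when adjusted over the list alone (adjusted p = 2.52e-11; adjusted p = 0.13 with an estimated correlation). Other CAR and PXR responsive genes rose in 3 of 11 cases, 6 when adjusted over the list alone (adjusted p = 0.000214; adjusted p = 0.00929 with an estimated correlation). Female-biased liver genes rose in 4 of 9 cases, also 4 when adjusted over the list alone (adjusted p = 0.000578; adjusted p = 0.144 with an estimated correlation), and conjugation enzymes in 5 of 27, or 5 with 1 fall when adjusted over the list alone (adjusted p = 0.000271; adjusted p = 0.32 with an estimated correlation). Of 566 genes called, 195 were higher and 371 lower. Counts with 1 array left out were 274 (corn oil replicate 1), 341 (corn oil replicate 2) or 257 (CPA replicate 1). Of the 20 largest changes 17 stayed called whichever array was left out, and Rnase2a, Cib3 and Cxcl9 did not.

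Under CPA in CARko/PXRko mice, which lack both receptors, Sult1e1 rose by 8.13 ± 0.69 (adjusted p = 1.07e-07) and Cyp17a1 by 4.97 ± 0.69 (adjusted p = 0.000121). Cyp2b10 rose by 3.51 ± 0.77 (adjusted p = 0.00812), from 6.46 ± 1.23 to 9.97 ± 1.45 (SD, n = 3), while Cyp2c55 fell by 2.08 ± 0.51 (adjusted p = 0.0177). Lcn2 (5.36 ± 0.78), Mt2 (5.19 ± 0.79), Mt1 (4.84 ± 0.80), Gadd45b (3.64 ± 0.35) and Orm3 (3.09 ± 0.51) rose. Other rises were in 1810053B23Rik (5.53 ± 0.72), Nnmt (3.90 ± 0.59), Scara5 (3.72 ± 0.62), Fmo2 (3.64 ± 0.45), Cyp2c39 (1.87 ± 0.31) and Cyp3a13 (1.71 ± 0.30). H2-Aa fell by 4.40 ± 0.47 (adjusted p = 3.95e-06), and Nrep (-4.31 ± 0.48), Serpina6 (-4.15 ± 0.42) and Serpina7 (-3.13 ± 0.67) fell as well. Car3 (-4.30 ± 0.81), the ketone enzyme Bdh1 (-3.54 ± 0.26), Vnn1 (-3.46 ± 0.77) and the male-biased Elovl3 (-3.18 ± 0.70) fell. The cell cycle gene Ccnd1 (-3.54 ± 0.67), the clock output gene Dbp (-3.47 ± 0.74) and Cyp2c23 (-2.02 ± 0.29) fell. Cyp3a11 was not called. The rise of Cyp2b10 was 4.60 by the mean of the gene's probe sets; it was no longer called with only the groups compared (3.51, adjusted p = 0.125), without corn oil replicate 1 (2.92, adjusted p = 0.0666) or without CPA replicate 2 (2.88, adjusted p = 0.0525). Without corn oil replicate 2, the control array with the most Cyp2b10 (7.73), the rise was 4.14 (adjusted p = 0.00494).

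Interferon-stimulated genes fell in 10 of 17 cases in CARko/PXRko mice under CPA, 15 when adjusted over the list alone (camera adjusted p = 1.23e-12; adjusted p = 0.0843 with an estimated correlation), and lymphocyte and antigen presentation markers in 4 of 8, also 4 when adjusted over the list alone (adjusted p = 0.000233; adjusted p = 0.0887 with an estimated correlation). Kupffer markers fell in 1 of 11 cases, or 4 with 1 rise when adjusted over the list alone, with a median of -0.19 (adjusted p = 0.12). Acute phase genes rose in 5 of 19 cases, 6 when adjusted over the list alone (adjusted p = 0.000157; adjusted p = 0.269 with an estimated correlation), and female-biased genes in 3 of 9, 4 when adjusted over the list alone (adjusted p = 0.000486; adjusted p = 0.143 with an estimated correlation). PPARA target genes fell in 4 of 17 cases, also 4 when adjusted over the list alone (adjusted p = 0.0404; adjusted p = 0.697 with an estimated correlation), and fatty acid synthesis genes in 3 of 18, also 3 when adjusted over the list alone (adjusted p = 0.0144; adjusted p = 0.688 with an estimated correlation). CYP2B and CYP2C enzymes went both ways, with 2 rises and 2 falls among 11, or 3 and 2 when adjusted over the list alone (adjusted p = 0.253). Of 702 genes called, 279 were higher and 423 lower (39.7% higher), against 412 higher and 256 lower (61.7% higher) with arrays centred on their median. Corn oil replicate 2, one of the controls, carried muscle transcripts (7.48). Without the 2 arrays with the most muscle transcripts 459 of the 702 calls were kept, and without the 4 arrays with them 442. With 1 array left out the counts were 282 (corn oil replicate 1), 464 (corn oil replicate 2), 368 (corn oil replicate 3) or 429 (CPA replicate 1). Of the 20 largest changes 17 stayed called whichever array was left out, and Dbp, Vnn1 and Elovl3 did not.

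**Figure D3:**
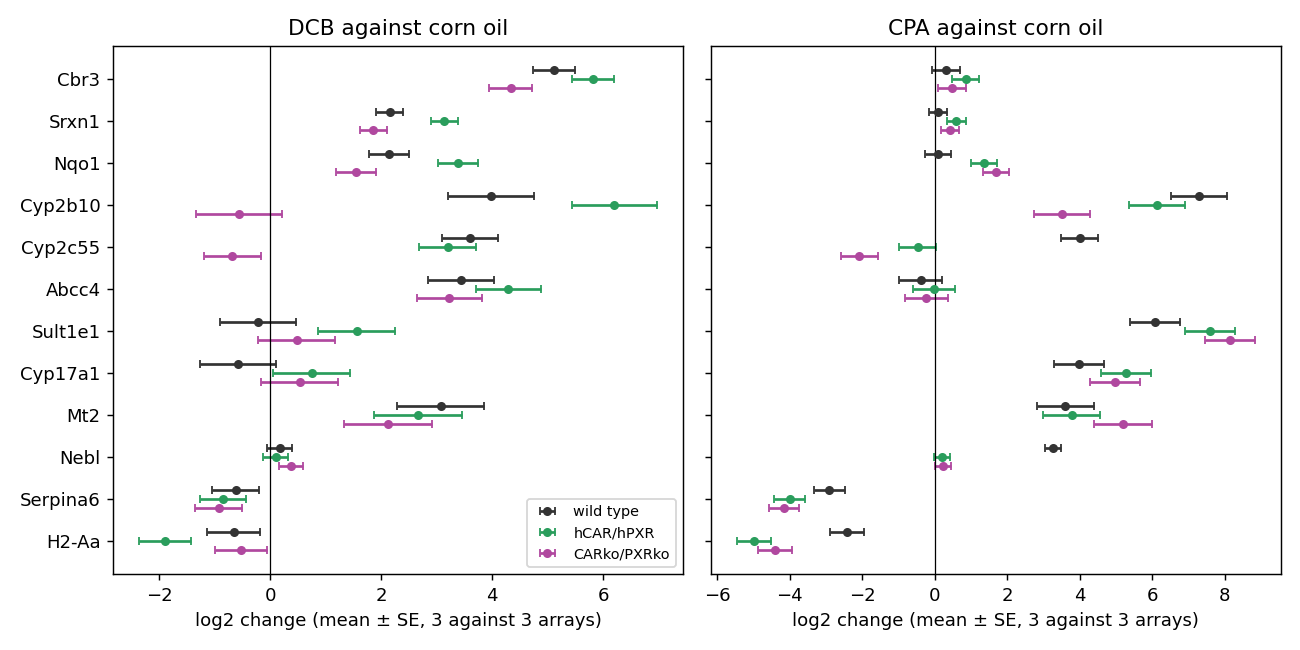
Log2 changes (points, mean ± SE, 3 against 3 arrays) of named genes under DCB and under CPA against corn oil, by genotype. Nebl rose by 3.27 under CPA in wild type mice and was 0.21 and 0.22 from corn oil in hCAR/hPXR and CARko/PXRko mice.

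The CPA effect was compared between genotypes, with the labelled duration of CPA differing between wild type (6 days) and CARko/PXRko mice (3 days). Nebl was called in wild type mice alone, and its effect was lower in hCAR/hPXR mice (-3.06 ± 0.31, adjusted p = 8.47e-06) and in CARko/PXRko mice (-3.04 ± 0.31, adjusted p = 9.48e-06). The effect on Cyp2c55 was lower too, in hCAR/hPXR mice (-4.46 ± 0.72, adjusted p = 0.00872) and in CARko/PXRko mice (-6.08 ± 0.72, adjusted p = 5.82e-05). In CARko/PXRko mice the effects on Ces2a (-2.42 ± 0.28, adjusted p = 5.14e-05), Bdh1 (-2.41 ± 0.37, adjusted p = 0.00246), Hsd17b6 (-4.60 ± 0.85, adjusted p = 0.0325), Cyp3a44 (-1.80 ± 0.35, adjusted p = 0.0496) and Nfs1 (-0.60 ± 0.12, adjusted p = 0.0486) were lower than in wild type mice. The stress gene Ddit4 (2.57 ± 0.35, adjusted p = 0.000598) and Med17 (1.31 ± 0.26, adjusted p = 0.0496) had higher effects there. In hCAR/hPXR mice the effects on Hsd17b6 (-4.43 ± 0.85, adjusted p = 0.0468) and Igfbp2 (-2.80 ± 0.51, adjusted p = 0.0255) were lower, and those on Tcim (3.25 ± 0.59, adjusted p = 0.0255), Gin1 (1.87 ± 0.31, adjusted p = 0.00872), Ddit4 (1.82 ± 0.35, adjusted p = 0.0488) and Slc8a1 (1.65 ± 0.26, adjusted p = 0.00872) were higher. Cyp2b10 differed by -1.16 ± 1.09 in hCAR/hPXR mice (adjusted p = 1) and by -3.78 ± 1.09 in CARko/PXRko mice (adjusted p = 0.369) and was not called. Other CAR and PXR responsive genes moved down as a group in CARko/PXRko against wild type mice (camera adjusted p = 0.00026; adjusted p = 0.00972 with an estimated correlation), with 1 of 11 lower and, when adjusted over the list alone, 5 lower and 1 higher. In all 8 genes were called for hCAR/hPXR and 9 for CARko/PXRko mice (unadjusted p-values under 0.05 numbered 628 and 967). Leaving out 1 array gave, for hCAR/hPXR mice, 1 gene without CPA wild type replicate 3, 4 without corn oil hCAR/hPXR replicate 1, corn oil wild type replicate 1 or CPA wild type replicate 2, and 5 without corn oil hCAR/hPXR replicate 3, corn oil wild type replicate 2, CPA hCAR/hPXR replicate 1 or 3, or CPA wild type replicate 1. For CARko/PXRko mice it gave 14 without CPA CARko/PXRko replicate 3 and 5 without corn oil wild type replicate 1 or 2 or CPA wild type replicate 1 or 3. Nebl stayed called for both genotypes whichever array was left out, as did Cyp2c55, Ces2a, Bdh1 and Ddit4 for CARko/PXRko mice, while every other named difference for hCAR/hPXR mice, and Hsd17b6, Med17, Cyp3a44 and Nfs1 for CARko/PXRko mice, lost their call at least once. Nfs1 was named after its value was seen. The counts of genes called for CPA itself were 143, 566 and 702 in wild type, hCAR/hPXR and CARko/PXRko mice. With only the groups compared they were 774, 398 and 136. Their order turned over with the fit, so these counts do not rank the responses of the genotypes.

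Many of the CPA changes were shared between genotypes, with CPA labelled as 6 days in wild type and hCAR/hPXR mice, 3 days in CARko/PXRko mice and corn oil as 3 days throughout. Between hCAR/hPXR and CARko/PXRko mice, 96 genes were higher in both against 4.3 for independent lists, 144 were lower in both against 12.3, and 1 went opposite ways. Wild type and hCAR/hPXR mice shared 36 higher genes against 0.9 and 66 lower genes against 2.3, and wild type and CARko/PXRko mice shared 34 against 1.4 and 55 against 2.7. Pearson's r across genes was 0.64 for wild type with hCAR/hPXR mice (simulated -0.57 to 0.64), 0.52 for wild type with CARko/PXRko mice (-0.58 to 0.51) and 0.62 for hCAR/hPXR with CARko/PXRko mice (-0.62 to 0.62). The simulated ranges again used a spread pooled over all groups.

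DCB and CPA effects within a genotype share 3 corn oil arrays, so part of any overlap may come from those controls. Wild type mice shared 9 higher genes against 0.4 for independent lists and 1 lower gene against 0.1, Cyp2b10, Cyp2c55 and Gstm3 among the former. In hCAR/hPXR mice 30 genes were higher under both compounds against 6.4, 124 were lower under both against 16.2, H2-Aa and Ugt2b38 among them, and 7 went opposite ways. CARko/PXRko mice shared 2 higher genes against 0.3. Pearson's r across genes was 0.35, 0.43 and 0.24 in wild type, hCAR/hPXR and CARko/PXRko mice, and simulations with no effect gave means of 0.45, 0.49 and 0.48 from the shared controls alone. The covariance of the changes was 0.038, 0.081 and 0.035 against simulated values of 0.031, 0.038 and 0.033. The simulations gave every group the spread of all arrays pooled. Mean correlation with the group was 0.993 on CPA wild type replicate 3 and 0.938 on DCB CARko/PXRko replicate 3. The simulated values therefore need not be those of each genotype.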

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

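The test of Nr1i3 against wild type arrays, the tests of Kupffer markers and the comparison of the count of 48 with those without single arrays were chosen only after the result was seen; the other tests here were written down before their results were seen.

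The effect of CPA differed from that in wild type mice for 8 genes in hCAR/hPXR mice, by a test of the difference itself. It was lower for Cyp2c55 (-4.46), Hsd17b6 (-4.43), Nebl (-3.06) and Igfbp2 (-2.80), and higher for Slc8a1 (1.65), Ddit4 (1.82), Gin1 (1.87) and Tcim (3.25). In CARko/PXRko mice it differed for 9 genes by the same test. It was lower for Cyp2c55 (-6.08), Hsd17b6 (-4.60), Nebl (-3.04), Ces2a (-2.42), Bdh1 (-2.41), Cyp3a44 (-1.80) and Nfs1 (-0.60), and higher for Med17 (1.31) and Ddit4 (2.57). Labelled duration (6 against 3 days) differs together with genotype in the CARko/PXRko comparison.

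A signal also appeared in data outside the comparisons. Of 3700 probe sets that passed the filter but are annotated to several genes or none, the counts called were 8, 57 and 5 for DCB in wild type, hCAR/hPXR and CARko/PXRko mice, and 32, 97 and 80 for CPA. They name no gene.

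Other splits of the same arrays were counted for every comparison. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05, and for each of these comparisons except the DCB effect in CARko/PXRko mice 1 split, the real one, reached the real count. The real counts were 94 and 978 for DCB in wild type and hCAR/hPXR mice and 143, 566 and 702 for CPA in wild type, hCAR/hPXR and CARko/PXRko mice, with a highest other split of 0 in each. For genotypes they were 3 (hCAR/hPXR), 5 (CARko/PXRko), 3 (PXRko) and 2 (CARko/PXRko against PXRko), with highest others of 0, 1, 0 and 1. For DCB in CARko/PXRko mice, 4 of the 10 splits reached the real count of 15 and the highest other called 550 genes, which points to a structure of the samples. For differences of effects, 100 splits were drawn. All 100 reached the real count of 0 for DCB in hCAR/hPXR and in CARko/PXRko mice (highest others 2 and 15). For CPA in hCAR/hPXR mice 1 split, the real one, reached the real count of 8 (highest other 6). That share is under 0.05, but it belongs to 1 of 14 comparisons. The count of 8 also fell to 1 without CPA wild type replicate 3. In CARko/PXRko mice 9 splits reached the real count of 9 (highest other 56). Chance cannot be excluded for either.

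Cyp2b10 rose under CPA in mice labelled as lacking CAR and PXR. Arrays from hCAR/hPXR mice were argued against by Tmem223, whose lowest CPA CARko/PXRko value lay 1.30 log2 units above the highest of the hCAR/hPXR arrays, and arrays from wild type mice by Nr1i3, whose highest value there lay at -2.46 from the lowest wild type array. Cross-hybridization with Cyp2b9 or Cyp2b13 stayed undecided. Their larger rise was 0.04, for Cyp2b13, whose probe set lay at 4.38 to 5.15 on all arrays. That is under the array medians of 5.36 to 5.44, too dim to exclude cross-hybridization. Cyp2b9 lay at 4.56, 4.52 and 3.97 on the CPA CARko/PXRko arrays, against 4.16, 7.68 and 4.22 under corn oil. The array with 7.68, replicate 2, was also the control with the most Cyp2b10 (7.73). A route to Cyp2b10 that needs neither receptor remains a hypothesis that may account for the rise. With only the groups compared the rise was again 3.51, with a standard error of 0.84 in place of 0.77. The call ended there (adjusted p = 0.125, in a range of 0.00237 to 0.125 over the alternatives). That fit rests on these 6 arrays alone. It has fewer residual degrees of freedom and called fewer genes, 136 against 702, which bears on the adjustment. Which of these ended the call was not tested.

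Fewer genes were called for DCB in CARko/PXRko than in wild type mice. RNA of other tissues could not be told from other differences between the arrays: 48 genes were called without the 2 arrays with the most muscle transcripts, against 15 with all arrays, but 72 without DCB replicate 1, which has no muscle signal (0.02), 69 without corn oil replicate 2 (7.48) and 20 without DCB replicate 3 (7.08). The first was 1 of 3 rules for leaving out arrays, all set after seeing the data, and the others gave 7 (without the 4 arrays with muscle transcripts) and 308 (without the 4 arrays least like their group), each with a single DCB array left; the latter is replicate 2, which carries squamous and muscle transcripts. A smaller response without the receptors stayed undecided: over the 978 genes called in hCAR/hPXR mice, the median signed change was 0.29 in CARko/PXRko and 0.37 in wild type mice, a ratio of 0.78 that ran from 0.69 to 0.87 with 1 array left out. Both explanations remain open.

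The antigen presentation genes H2-Aa, H2-Ab1 and Cd74 fell under CPA in each genotype. Their list, which also holds lymphocyte markers, had medians of -1.28, -1.82 and -1.12 in wild type, hCAR/hPXR and CARko/PXRko mice (adjusted p = 0.0428, adjusted p = 0.0121 and adjusted p = 0.0887 with an estimated correlation). Fewer Kupffer cells as the whole cause was argued against in CARko/PXRko mice, where the Kupffer list had a median of -0.19. In wild type and hCAR/hPXR mice its medians were -0.78 and -1.24, which go with fewer Kupffer cells there (adjusted p = 0.19 and adjusted p = 0.13 with an estimated correlation), so that explanation stays open in both. Fewer dendritic and B cells could not be told from a fall per cell: over 6 genes of these cells the medians were -0.35, -0.63 and -0.26, and 0, 2 and 2 fell, the B cell genes Cd79b and Cd22 in both genotypes with falls. The dendritic cell genes Itgax, Flt3 and Siglech were not called, with 0.10 ± 0.18, 0.17 ± 0.17 and 0.08 ± 0.13 in CARko/PXRko mice. Their corn oil means there, 5.30, 5.77 and 5.42, lay near the array medians, too dim to exclude fewer such cells. Fewer cells, or less transcript in each, may each account for the pattern.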

How the results depend on the processing

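All 3 rules for leaving out arrays were chosen after seeing the data, the one for the 2 arrays after seeing the counts of the others; the remaining alternatives were planned. No called gene changed sign where an alternative was run on it, and no list was called in opposite directions by 2 fits. The direction of lists changed in 3 results with fry, 2 with the replicate block and 4 with the mean of the gene's probe sets. These may include called lists. The balance of rises and falls also turned over. The share higher went from 43.0% to 64.2% for DCB in hCAR/hPXR mice, from 43.4% to 50.7% for CPA in wild type and from 39.7% to 61.7% for CPA in CARko/PXRko mice with arrays centred on their median. For DCB in hCAR/hPXR mice it was also 52.0% with quantile normalization again, 57.3% with only the groups compared and 50.5% without the 4 arrays least like their group. For every gene count below, the cause was not tested unless given. A threshold of 2-fold, by construction, left 37 and 240 genes for DCB in wild type and hCAR/hPXR mice and 87, 288 and 306 for CPA in wild type, hCAR/hPXR and CARko/PXRko mice. Array weights, whose fit stopped before its convergence tolerance was met, gave 969, 2993 and 168 for DCB and 1798, 1147 and 290 for CPA in the same order of genotypes, 10, 205, 41 and 22 for the genotypes under corn oil (hCAR/hPXR, CARko/PXRko and PXRko against wild type, then CARko/PXRko against PXRko), 3 for the DCB difference in CARko/PXRko mice and 81 for the CPA difference in hCAR/hPXR mice. With only the groups compared, where fewer arrays estimate the spread, the counts were 82 for DCB in hCAR/hPXR, 0 for DCB in CARko/PXRko (706 unadjusted p-values under 0.05 in that limma fit), 774 for CPA in wild type, 136 for CPA in CARko/PXRko and 1 for CARko/PXRko against PXRko mice.

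Without the 4 arrays least like their group, DCB gave 238 in wild type and 308 in CARko/PXRko mice, CPA gave 361 and 983 in wild type and hCAR/hPXR mice, genotypes against wild type gave 5, 14 and 6, and the differences gave 55 (DCB, CARko/PXRko), 17 and 67 (CPA, hCAR/hPXR and CARko/PXRko). Without the 4 arrays with muscle transcripts, the counts were 7 for DCB in CARko/PXRko, 9 for CARko/PXRko against wild type and 1 against PXRko mice. Both rules leave the DCB CARko/PXRko group with 1 array, which is assumed to vary like the other groups. Without the 2 arrays with the most muscle transcripts these were 48, 8 and 1, and PXRko against wild type gave 5. The DCB difference in CARko/PXRko mice, 0 as reported, was 2 with a filter at the 75th percentile, 1 with quantile normalization again, 1 with arrays centred on their median, 2 with the mean of the gene's probe sets and 2 with trend and robust; the CPA difference there was 5 with trend and robust.

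With 1 array left out there were 37 to 115 and 337 to 1056 genes for DCB in wild type and hCAR/hPXR mice, 6 to 72 in CARko/PXRko mice, and 38 to 112, 257 to 562 and 282 to 929 for CPA in the same order. The ranges were 3 to 4, 3 to 7, 1 to 2 and 1 to 1 for the genotypes, and 0 to 0, 0 to 3, 1 to 10 and 5 to 14 for the differences (DCB then CPA, hCAR/hPXR then CARko/PXRko). The labels give arrays a number in common and nothing else. After removal of group means, the median correlation of same-numbered arrays was 0.012 over 135 pairs, of which 31.1% lay over 0.1. Of 30 arrays, 16 correlated best with their own number, and 5.8% of 1000 shuffles of the numbers within groups reached 16. The median for different numbers was 0.008, and 33.7% of the shuffles had a median of same-numbered arrays as high as the real one. As not every pair exceeded 0.1, the numbers were not used as pairs. That rule does not exclude a batch shared by some arrays with the same number. The replicate block gave 107, 954, 13, 148, 549 and 711 for the 6 treatment effects. Among named genes and correlations of effects, leaving out 1 array kept 12465 results, weakened 497, strengthened 76 and moved 321. The results kept include genes called in neither fit, and each gene counts once per comparison and array, so they do not measure how many calls hold. For lists, camera with an estimated correlation kept 58 results and weakened 125, and fry, by direction, kept 79, weakened 101 and moved 3. Signal near background limits dim genes, and 3 arrays per group limit all comparisons.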

Other observations

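No test here was chosen after its result was seen, but the patterns themselves were noticed in the data and the gene lists were written afterwards.

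Mt2 and Ddit4 rose under CPA in each genotype and Lcn2 in hCAR/hPXR and CARko/PXRko mice, with Ddit4 at 1.04 in wild type, 2.86 in hCAR/hPXR and 3.61 in CARko/PXRko mice. A glucocorticoid-type response may be involved. Over 11 glucocorticoid-responsive genes, camera with an estimated correlation, adjusted over the 3 genotypes, gave 0.0889 in wild type, 0.0108 in hCAR/hPXR and 0.0108 in CARko/PXRko mice. The medians were 0.32, 0.48 and 0.33, and 1, 3 and 4 genes rose. Fkbp5 rose by 2.04 ± 0.29, 3.12 ± 0.29 and 3.13 ± 0.29 in the same order. The list was not called up in wild type mice, so the hypothesis stays undecided.

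Corn oil CARko/PXRko replicate 2 had higher Cyp2b9 (7.68 against 4.16 and 4.22) than the other arrays of its group, as female liver would, and less of the male-biased Hsd3b5 (5.46 against 12.96 and 13.13), Elovl3 (8.75 against 12.17 and 12.01) and Cyp7b1 (10.07 against 13.34 and 13.73). It is a control array of both treatment effects in CARko/PXRko mice. Hsd3b5 was also low on DCB CARko/PXRko replicate 2 (4.97) and CPA CARko/PXRko replicate 3 (5.00). A female mouse as the source of the corn oil array was argued against by Xist, at -0.03 from the median of the other 29 arrays. The Y chromosome genes Eif2s3y (9.78), Kdm5d (7.20) and Uty (7.46), read after that test, lay within the range of the other arrays. No other cause was tested. Corn oil CARko/PXRko replicate 2 also carried skeletal muscle transcripts, with a median of 7.48 log2 units above wild type corn oil over 17 genes. Over 5 brown fat genes, of which liver also expresses Elovl3, array medians ran from -0.45 to 0.62.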
